A study of Rattus norvegicus with 6 samples.

How the data were processed

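Renal cortex RNA of 6 male Sprague-Dawley rats, 3 given corn oil and 3 given o-anthranilic acid at 1000 mg/kg/day for 4 weeks, was labelled with Cy3 and hybridised to single-colour Agilent arrays, 1 array per animal, per the labels. The labels call the 3 samples of each group biological replicates. Spots were quantified with Agilent Feature Extraction 10.7, per the submitters' processing notes. The deposited scanner files hold spot brightness as intensity on a linear scale, per the file headers: a background-subtracted and detrended signal that is not normalised between arrays, and the median signals of spot and local background. The authors' deposited value table holds a ratio, which by comparison with the scanner files is the processed signal divided by the array's own 75th percentile, on a linear scale and not centred per gene. Its column medians were 0.104, 0.106 and 0.103 for the vehicle samples and 0.106, 0.104 and 0.103 for the treated samples. The columns of vehicle replicates 1, 2 and 3 matched the scanner files of vehicle replicates 3, 1 and 2, and those of treated replicates 1, 2 and 3 matched treated replicates 3, 1 and 2. Which numbering holds is unknown. Replicates are named here by scanner file, and the groups are the same either way.

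Each array held 62976 spots, of which 61657 were non-control probes. 84 probes named for external RNA controls and 47 with an outlier flag were left out, no spot was saturated, and 61526 were used. Of these, 27435 were named through RefSeq accessions in a table of current symbols, giving 15277 symbols, and 34091 were not named. No coordinates are given, since the genome build of the array design differs from that of the naming table. The processed signal was put on the log2 scale and each array's 75th percentile was subtracted. A probe was kept if it was well above background on at least 3 of 6 arrays. Each gene was represented by its kept probe with the highest mean signal. Of 7879 features with more than 1 kept probe, 2900 had probes with log2 fold changes of both signs, and 5 had probes beyond 0.5 in both directions.

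Treated and vehicle animals were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment over all features, threshold 0.05). Lists of genes were fixed before the data were examined, for kidney segments, other cell types and pathways, and 39 had at least 5 measured members. Lists were tested with camera with a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. fry tests whether the genes of a list move, on balance, in 1 direction. Members were also adjusted over the list alone. Further R packages were statmod 1.5.0, jsonlite 2.0.0 and, for reading the files, data.table (version 1.17.8). The gene test of limma and the list tests by camera and fry were tested on simulated data with the size and spread of this comparison, in 10 simulations over 30709 features. limma called 4.4% of features changed by 0.5 on the log2 scale, 57.0% of those changed by 1, 90.0% by 2 and 93.8% by 3, with 69 false calls in all simulations together. Each simulation held 50 changed features of each size and several shifted lists. The shares called depend on how many features change, so they do not give the share that would be found in these data. Lists shifted by 0.25 were called in 95.0% of cases with the preset correlation, 68.0% with an estimated one and 86.0% by fry, and unshifted lists in 1.25%, 0% and 4.58%. Simulated genes varied independently of each other. In the data the estimated correlation was 0.169 for cholesterol synthesis, 0.354 for the interferon list and -0.0132 for heat shock. The simulated rates therefore do not show how often the preset correlation calls unshifted lists of correlated genes.

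By a rule fixed before the data were examined, named genes were to be those past the threshold with the largest changes, the leading members of each list, and a fixed set of kidney and pathway genes. Since no gene passed, the rule gave the 5 genes with the smallest p in each direction and the fixed set. Members past the threshold adjusted over the list alone were added, and other list members were named as examples after their values were seen. These include Hmox1, Gclm, Gclc, Herpud1, Atf4, Abcc2, Slc17a3, Slc22a7, Alas2, Hbb, Hbb-b1, Usp18, Irf7, Oas1a, Isg15, Egr1 and Fos.

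Alternatives chosen before the data were examined were normexp background correction (offset 50), quantile normalisation, median scaling, the 75th percentile over probes well above background on all 6 arrays, the authors' values, no filter, a filter of all 6 arrays, the mean of a gene's probes, every probe, a variance trend with robust fit, array weights, the replicate number as a block, the slide as a block, the slide that holds both groups alone, and each array left out. The scanner files used here held no mean spot signal, so normexp took the median spot and background signals in place of the mean. A common floor for dim signals, named genes only, and counts over a list alone in each setting were added after the data were seen. Some genes of the lists and of the fixed set, and 1 added alternative that concerns 1 of them, are not reported here.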

Results

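Total RNA of the renal cortex, the outer kidney with the glomeruli and most of the proximal tubule, was measured in 6 male Sprague-Dawley rats on single-colour (Cy3) Agilent arrays. 3 animals had received corn oil, the vehicle, and 3 had received o-anthranilic acid at 1000 mg/kg/day, both for 4 weeks. o-Anthranilic acid is ortho-aminobenzoic acid, which mammals also form from tryptophan through the kynurenine pathway. The share of probes well above background was 69.1%, 69.3% and 66.0% on the vehicle arrays and 63.7%, 68.3% and 64.7% on the treated arrays. After filtering, 30709 features were tested, of which 11913 were named genes and 18796 were transcripts with no symbol. The number of arrays limited the precision, and the median standard error of a log2 fold change was 0.11.

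The comparison of treated with vehicle animals asked which renal cortex transcripts changed with o-anthranilic acid. Genes of cholesterol synthesis and targets of Nrf2, the transcription factor of the antioxidant response, rose as groups in treated animals by camera with its preset correlation, with an adjusted p of 0.405 for each with an estimated correlation. Genes of the interferon response and of the unfolded protein response fell as groups by the same test, with adjusted p of 0.619 and 0.405 with an estimated correlation. Some splits of the 6 arrays that mixed the groups gave the interferon list a smaller camera adjusted p than the real 1.08e-05, down to 1.82e-08. Sqle (NM_017136), squalene epoxidase, had a 1.62-fold higher mean in treated than in vehicle animals (log2 fold change 0.70 ± 0.11, SE, n = 3 per group), and Gstp1 (NM_012577), a glutathione transferase, a 2.62-fold higher mean (1.39 ± 0.24). No single gene passed the threshold when adjusted over all features: limma with Benjamini-Hochberg adjustment called 0 of 30709, 0 higher and 0 lower, with a smallest adjusted p of 0.0813. At an unadjusted p under 0.05 there were 2548 features, 1062 higher and 1486 lower, where chance alone would give 1535. The share that was higher was 41.7%, against 47.9% with normexp background correction and 51.6% of 3017 features with no filter on dim probes. The treated and vehicle values did not overlap for 4516 features, or 14.7%, where chance gives 10%. limma called 5 features with a variance trend and robust fit, 5 with normexp background correction and 3 with the slide as a block. Treated replicate 2 was alone on its slide, so the slide as a block is the same fit as leaving out that array. limma called 3 without vehicle replicate 2 and 2 without treated replicate 1.

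Of the 39 gene lists fixed beforehand, camera with its preset correlation called 4 higher and 4 lower, and none of the 8 was called with an estimated correlation or by fry. Without vehicle replicate 3 the lists called lower were 2. The list of cholesterol synthesis had 20 measured members, all with a log2 fold change above 0 and a median of 0.26. Camera gave it an adjusted p of 2.36e-10, and the adjusted p was 0.405 with an estimated correlation. The list mean was higher on each of the 3 treated arrays than on any vehicle array. List means did not overlap between the groups, in either direction, for 7 of the 39 lists, 5 of them called. Chance gives 10% for a single list. None of the cholesterol synthesis members passed over all features, and 8 were past the threshold, all higher, when adjusted over the list alone. Sqle had a log2 fold change of 0.70 ± 0.11 (SE), Hsd17b7 (NM_017235) of 0.58 ± 0.11, Cyp51 (NM_012941) of 0.36 ± 0.08 and Sc5d (NM_053642) of 0.31 ± 0.07. These genes encode enzymes of sterol synthesis. Idi1, Insig1 and Hmgcs1, also among the 8, stood at 0.37, 0.36 and 0.25. The members past the threshold adjusted over the list alone were 4 without vehicle replicate 2, 3 without vehicle replicate 3, 2 without treated replicate 1 and 3 without treated replicate 3. With the slide as a block the median was 0.26 with a camera adjusted p of 5.65e-11.

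**Figure D1:**
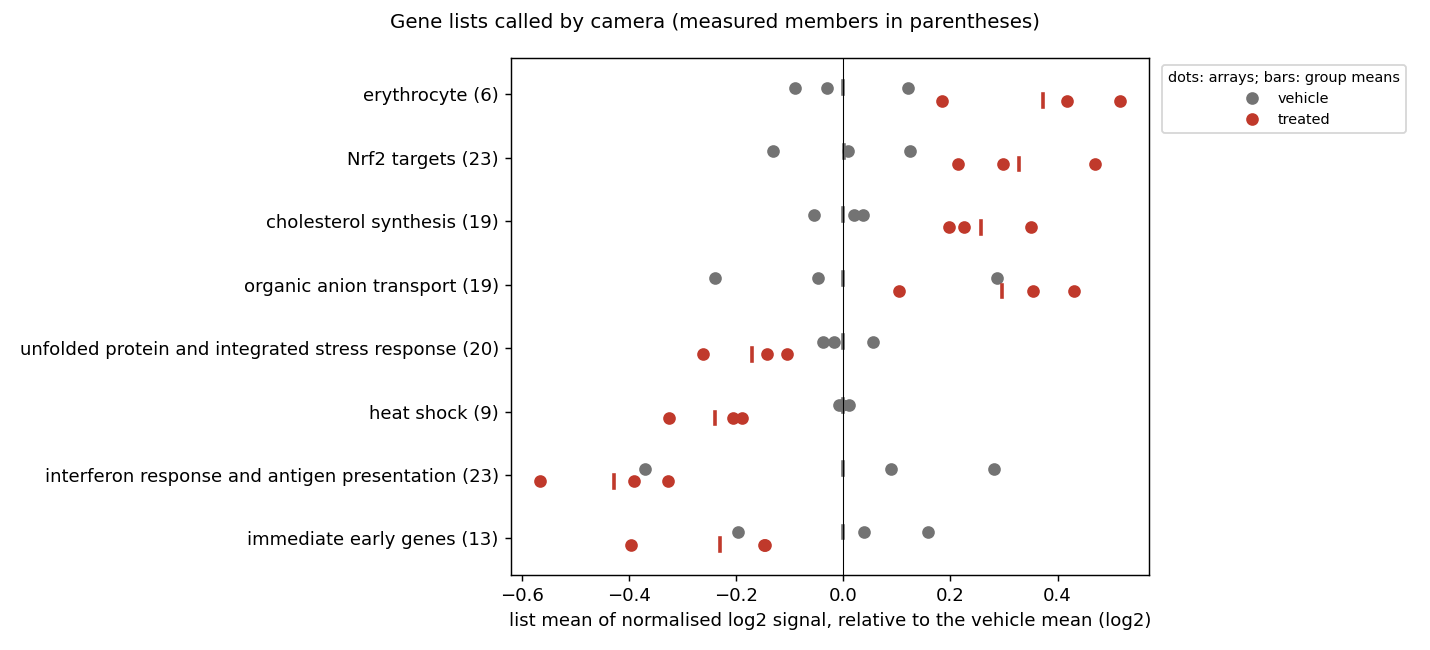
Mean normalised log2 signal of the members of each list called by camera, relative to the vehicle mean (horizontal axis, log2 units), for each of the 6 arrays (dots) with the group means (bars). Cholesterol synthesis is drawn without 1 dim member, and its 3 treated arrays lie between 0.20 and 0.35, above the 3 vehicle arrays, which lie between -0.06 and 0.04. Nrf2 targets are drawn with Hmox1, which was far higher in treated replicate 3 than on any other array. The Nrf2 dot of that array, at 0.47, therefore rests in part on 1 probe.

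Nrf2 targets rose as a list, with a median log2 fold change of 0.26 over 23 members and a camera adjusted p of 0.000324. The adjusted p was 0.405 with an estimated correlation. None of the members passed over all features, and 6 were past the threshold adjusted over the list alone, 5 higher and 1 lower. Gstp1 had a log2 fold change of 1.39 ± 0.24 (SE). Nqo1 (NM_017000), a quinone reductase, stood at 1.28 ± 0.28, and Akr7a3 (NM_013215), an aldehyde reductase, at 0.80 ± 0.12. Abcc4, an efflux transporter, and Trib3, a pseudokinase, had log2 fold changes of 0.50 and 0.33, the latter 0.15 after normexp background correction. The member that went the other way was Akr1b8 (NM_173136), an aldo-keto reductase, at -1.89 ± 0.17, which is 3.70-fold lower. Gclm and Gclc, the subunits of the enzyme that starts glutathione synthesis, had log2 fold changes of 0.91 ± 0.32 and 0.70 ± 0.42 and did not pass, and Gclc stood at 0.35 without vehicle replicate 2 and at 1.11 without vehicle replicate 1. Hmox1, haem oxygenase, was at 5.11 in treated replicate 3 and between -1.55 and -1.42 on the other 5 arrays, and its log2 fold change of 2.21 ± 1.77 was 0.03 without that replicate. The members past the threshold adjusted over the list alone were 3 without vehicle replicate 3, 3 without treated replicate 2 and 3 without treated replicate 3. With the slide as a block the list's median was 0.24 with a camera adjusted p of 0.00344.

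Organic anion transport, the route by which the proximal tubule secretes organic acids, rose as a list with a median log2 fold change of 0.24 over 19 members and a camera adjusted p of 0.00146, and the adjusted p was 0.428 with an estimated correlation. None of its members passed, over all features or adjusted over the list alone. Abcc2, an apical efflux transporter, had a log2 fold change of 0.74 ± 0.18 (SE), Slc17a3 of 0.35 ± 0.09 and Slc22a7 of 1.38 ± 0.62. Slc22a7 stood at 0.91 without vehicle replicate 2 and at 1.97 without vehicle replicate 1. The main basolateral uptake carriers Slc22a6 and Slc22a8 had log2 fold changes of 0.11 ± 0.09 and 0.03 ± 0.07, and ranged from 0.06 to 0.18 and from -0.01 to 0.05 without 1 array. The list means of the groups overlapped, with treated replicate 3 at 0.10 and vehicle replicate 1 at 0.29 relative to the vehicle mean, and the median was 0.15 without vehicle replicate 2. The straight proximal tubule list, which shares Slc22a7 and other Slc22 carriers with it and was not called, had similar means. It stood at 0.215, -0.202 and -0.013 on the vehicle arrays and 0.392, 0.343 and 0.158 on the treated arrays. Organic anion transport stood at 0.287, -0.239 and -0.048, and at 0.355, 0.431 and 0.103. Because of the shared genes the 2 lists are not separate evidence. Organic anion transport also shares Abcc4 with the Nrf2 targets. Erythrocyte genes rose as a list of 6 members with a median of 0.37 and a camera adjusted p of 0.00341, and the adjusted p was 0.405 with an estimated correlation. None of these members passed either test, and Alas2, Hbb-b1 and Hbb had log2 fold changes of 0.62, 0.43 and 0.31. With the slide as a block the medians were 0.21 for organic anion transport, with a camera adjusted p of 0.0228, and 0.34 for erythrocyte genes, with 0.0156.

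Genes of the interferon response and antigen presentation fell as a list, with a median log2 fold change of -0.34 over 23 members and a camera adjusted p of 1.08e-05. The adjusted p was 0.619 with an estimated correlation. None of the members passed over all features or adjusted over the list alone. Usp18, Irf7, Oas1a and Isg15 had log2 fold changes of -1.12, -1.06, -0.99 and -0.83, with standard errors of 0.44, 0.41, 0.36 and 0.33. Without vehicle replicate 1 they stood at -0.76, -0.66, -0.70 and -0.58, and without vehicle replicate 2 at -1.60, -1.46, -1.34 and -1.20. The other 2 kept probes of Usp18, not used in the test, had log2 fold changes of -0.98 and -0.415 over all arrays. The list means of the groups overlapped: relative to the vehicle mean the vehicle arrays stood at 0.28, -0.37 and 0.09 and the treated arrays at -0.57, -0.39 and -0.33. With the slide as a block the median was -0.39 with a camera adjusted p of 3.56e-06. The lymphocyte list, with a median of -0.01, and the list of macrophages and myeloid cells, with -0.10, were not called. Their medians were -0.15 and -0.24 with the slide as a block, with camera adjusted p of 0.104 and 0.0602. Without treated replicate 1 the gene list lymphocyte stood at 0.15 and was called higher, with a camera adjusted p of 0.00193, and the gene list macrophage and myeloid cell stood at -0.05. The lymphocyte list means of the treated arrays were -0.54, 0.35 and 0.14 relative to the vehicle mean.

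The list of the unfolded protein and integrated stress responses fell, with a median log2 fold change of -0.21 over 20 members and a camera adjusted p of 0.000324, and the adjusted p was 0.405 with an estimated correlation. None of its members passed either test. Herpud1, an endoplasmic reticulum protein, had a log2 fold change of -0.53 ± 0.11 (SE), and Atf4, the transcription factor of the integrated stress response, of -0.34 ± 0.08. Trib3 went the other way, at 0.33. Heat shock genes fell with a median of -0.26 over 9 members and a camera adjusted p of 0.0238, and the adjusted p was 0.405 with an estimated correlation. Hspa1a (NM_031971), an inducible chaperone, was the 1 member past the threshold adjusted over the list alone, at -0.95 ± 0.17. Immediate early genes fell with a median of -0.37 over 13 members and a camera adjusted p of 0.0184, and the adjusted p was 0.619 with an estimated correlation. Dusp1, a phosphatase of mitogen-activated kinases, was the 1 member past the threshold adjusted over that list alone, at -0.69 ± 0.15. It stood at -0.37 after normexp background correction. Egr1 and Fos had log2 fold changes of 0.64 ± 0.30 and 0.29 ± 0.38. The list means of the immediate early genes overlapped between the groups. With the slide as a block the medians were -0.18, -0.19 and -0.32 for these lists, with camera adjusted p of 0.0228, 0.0392 and 0.165, so the call of the immediate early genes was lost in this fit, which leaves out treated replicate 2. The heat shock call was lost without vehicle replicate 2, at a camera adjusted p of 0.0791, and without vehicle replicate 3, at 0.0566. The immediate early call was also lost without vehicle replicate 3, at 0.276.

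The named genes with the smallest p among those with higher values in treated animals were Guca2b, Tm7sf2, Ascl2, Akr7a3 and Stard4. Guca2b (NM_022284), which encodes uroguanylin, a peptide that acts on salt transport in gut and kidney, had a log2 fold change of 1.85 ± 0.16 (SE), or 3.61-fold, and an adjusted p of 0.120 from limma. Its normalised log2 signal was -0.19 ± 0.07 (SD, n = 3) in vehicle and 1.66 ± 0.30 (SD, n = 3) in treated animals. Tm7sf2 (NM_001013071), a sterol reductase, stood at 0.74 ± 0.07 and Stard4 (NM_001106159), a sterol carrier, at 0.52 ± 0.08. Neither was on the list of cholesterol synthesis. Ascl2, a transcription factor, stood at 0.56 ± 0.08 and at 0.32 after normexp background correction. Among those with lower values the smallest p belonged to Mageb3, Akr1b8, Plaat1, Cnnm1 and Kctd8. Plaat1 (NM_001105871), a phospholipid-modifying enzyme, had a log2 fold change of -1.87 ± 0.18, or 3.65-fold lower, with a limma adjusted p of 0.148, and -1.01 after normexp background correction. Cnnm1 stood at -1.02 ± 0.12. Mageb3 and Kctd8, at -0.95 and -0.80, were well above background on 3 vehicle arrays and on 1 treated array, and stood at -0.32 and -0.25 after normexp background correction. None of these 10 genes passed the threshold.

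Markers of kidney injury did not pass. Havcr1 (NM_173149), which encodes the tubular injury protein KIM-1, had a log2 fold change of 0.72 ± 0.19 (SE), with a limma adjusted p of 0.479. Its probe was well above background on 3 vehicle and 3 treated arrays, and the log2 fold change was 0.25 after normexp background correction. Lcn2, Clu and Spp1 had log2 fold changes of 0.15 ± 0.39, 0.22 ± 0.33 and 0.28 ± 0.22. Without 1 array they ranged from -0.28 (without vehicle replicate 1) to 0.38, from 0.06 to 0.51 and from 0.15 to 0.51. Timp1, an inhibitor of matrix proteases, stood at -0.02 ± 0.13, and Cdkn1a, a cell cycle inhibitor, at -0.07 ± 0.11. The other kept probe of Cdkn1a, not used in the test, stood at -0.54, so the probes of this gene differed. Kmo and Kynu, enzymes of the kynurenine pathway, stood at 0.06 ± 0.08 and -0.03 ± 0.09, with 95% intervals from -0.14 to 0.26 and from -0.24 to 0.18. Umod of the thick ascending limb and Aqp2 of the collecting duct stood at 0.00 ± 0.22 and -0.21 ± 0.10. Without 1 array Umod ranged from -0.23 to 0.16 and Aqp2 from -0.27 to -0.14, Timp1 from -0.09 to 0.10 and Cdkn1a from -0.17 to 0.02. Cyp1a1, the classic target of the aryl hydrocarbon receptor, was not well above background on any array and was not tested.

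The list of tubular injury genes had a median log2 fold change of 0.02 over 26 members and a camera adjusted p of 0.411, and its median ranged from -0.02 to 0.08 over the other settings. The early proximal tubule list stood at -0.01 and the straight segment list at 0.15, with camera adjusted p of 0.619 and 0.127. Without vehicle replicate 1 the gene list proximal tubule, straight segment stood at 0.22 and was called higher, with an adjusted p of 0.0124. Aryl hydrocarbon receptor targets had a median of 0.13, or 0.04 with the mean of a gene's probes, and an adjusted p of 0.178, with Nqo1 past the threshold adjusted over the list alone. Glycine conjugation and glucuronidation, the reactions that prepare aromatic acids for excretion, had a median of 0.11 and an adjusted p of 0.204. The median ranged from -0.02 (without vehicle replicate 2) to 0.29 (with the slide as a block, adjusted p 0.0931) over 21 other settings, and the list was called in 1 of them, the mean of a gene's probes (adjusted p 0.0388 for the gene list glycine conjugation and glucuronidation). The lists of tryptophan to kynurenine and NAD, at -0.03, of p53 targets, at -0.05, of proliferation, at 0.02, and of the respiratory chain, at -0.05, were not called. The median of the tryptophan list ranged from -0.09 to -0.02 over 21 other settings, and it was called in none of them. The gene list proliferation was called without treated replicate 3, at 0.10 with an adjusted p of 0.0409, and the gene list respiratory chain without vehicle replicate 1, at -0.08 with 0.0300, and with no filter, at -0.05 with 0.0373. The podocyte list stood at -0.10 with an adjusted p of 0.0758, and the adjusted p was 0.724 with an estimated correlation. It was called lower in 7 of 21 other settings, among them no filter (adjusted p 0.0204), a filter of all 6 arrays (0.0162), the mean of a gene's probes (0.0151), and without vehicle replicate 1 (0.0300), vehicle replicate 2 (0.0152) or treated replicate 3 (0.0126), while without vehicle replicate 3 the gene list podocyte stood at -0.02. Magi2, a scaffold protein, was its 1 member past the threshold adjusted over the list alone, at -0.69 and at -0.12 after normexp background correction. The list of adipose and adrenal tissue had a median of 0.18, which was -0.12 without vehicle replicate 3 and 0.31 with the mean of a gene's probes. In it Adipoq was higher and Cyp11b2 lower when adjusted over the list alone, at 0.36 and -0.47, and Cyp11b2 was not well above background on any treated array and stood at -0.16 after normexp background correction. The list of fibroblast, mesangium and matrix genes had a median of 0.11 and an adjusted p of 0.160, and the adjusted p was 0.791 with an estimated correlation. With the slide as a block, which leaves out treated replicate 2, the median was 0.23 and the camera adjusted p 0.0122, and without treated replicate 3 the median was 0.01. Housekeeping genes had a median of -0.01. Median and test differed in sign for complement (median -0.04, test higher), for the distal convoluted and connecting tubule (0.06, test lower) and for targets of the xenobiotic receptors CAR and PXR (-0.01, test higher), and the gluconeogenesis list had a median of -0.02 and a mean of 0.06. None of these 4 lists was called.

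3 vehicle arrays and treated replicates 1 and 3 shared 1 slide, on which the vehicle arrays lay in 1 row and the treated arrays in the other, and treated replicate 2 lay on the other slide. The mean signal of the negative control spots was 3.81, 3.85 and 5.28 on the vehicle arrays and 7.62, 3.93 and 7.51 on the treated arrays. Of 70 named genes, 67 had the same sign with the slide as a block, and the exceptions were Timp1, Umod and Mt1, whose log2 fold changes were near 0. That fit reuses the arrays of the main fit less treated replicate 2, and many of these genes were chosen by their values there. Group and slide row coincide in it, so the count cannot address slide position.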

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

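A common floor, named genes only and the counts over a list alone were chosen after the results were seen. Counts of features past the threshold moved from 0 to 5 (2 higher, 3 lower, 4 at least 2-fold) with normexp and with the variance trend and robust fit, to 1 (lower, 1 at least 2-fold) with a filter of all 6 arrays, to 2 (2 lower, 2 at least 2-fold) with the mean of a gene's probes, and to 3 (3 lower, 3 at least 2-fold) with the slide as a block or within the slide that holds both groups. Leaving out 1 array gave 0 to 3 past the threshold, 0 to 3 lower and 0 to 3 at least 2-fold. The cause was not tested. Guca2b and Akr1b8 were called with normexp and with the trend, Plaat1 with normexp and with the mean of probes, and Tm7sf2 with the trend. Fam111a, named after its values were seen, was called with the slide as a block, as were 2 unnamed transcripts, and Cryga and Crygd, so named too, without vehicle replicate 2. Features at an unadjusted p under 0.05 were 1108 among named genes only, where fewer features were tested, and 2082 to 2745 without 1 array.

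Lists called lower were 8 without a filter and 2 to 6 without 1 array, and the lists called were 0 higher and 0 lower with an estimated correlation and by fry. Cholesterol synthesis, Nrf2 targets, organic anion transport, erythrocyte genes, the interferon response and the unfolded protein response were called in all 21 other settings, of which the slide as a block, the slide that holds both groups and leaving out treated replicate 2 are 1 and the same fit. The authors' values, also among the 21, have the same signal and scaling as the main setting and nearly repeat it. They gave the same count of 2548 features at an unadjusted p under 0.05, so they are no separate check. The highest camera adjusted p over the other settings were 1.1e-06, 0.0285, 0.0285, 0.0367, 0.00115 and 0.0228. The heat shock list was called in 19 of 21 and immediate early genes in 17 of 21, lost in that same fit and without vehicle replicate 3, and lists were not run with every probe. The gene list lymphocyte turned from -0.01 to 0.15 without treated replicate 1, where it was called higher (camera adjusted p 0.00193), and ranged from -0.15 to 0.15 without 1 array. The cause was not tested. Cholesterol synthesis members past the threshold adjusted over the list alone were 5 without a filter, 5 with array weights and 2 to 7 without 1 array. Nrf2 targets were 3 with the slide as a block or within its slide and 3 to 9 without 1 array. A change of direction with no call on either side, found 32 times for genes (sign of the fold change) and 52 times for lists (direction of the test), was not counted as a reversal.

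Lists not called in the comparison were called in some settings: podocyte in 7 of 21 (the replicate number as a block among them, adjusted p 0.0326), ribosomal protein genes in 4, endothelial cell in 3, fibroblast in 3 (1 fit), thick ascending limb and respiratory chain in 2 each, and proliferation, the straight proximal tubule and glycine conjugation in 1 each. The cause was not tested.

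With the replicate number as a block, features past the threshold were 0, cholesterol synthesis members past it over the list alone 2 and Nrf2 targets 3. The deviations of same-numbered arrays correlated at 0.0234, -0.0437 and -0.0207, and not every array correlated best with its own number. Deviations from a mean of 3 arrays depend on each other, so these values cannot show whether the numbers mark pairs. Signal over background limits dim genes, with 63.7% to 69.3% of probes well above it.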

Other observations

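The tests on other splits of the samples, on dim signals and on slide position were chosen after the results were seen, and the form of the dim-signal, position, Nrf2 and Hmox1 tests was changed after a first run. The lists of liver X receptor targets and fatty acid synthesis were written after the fixed lists were seen and before their own values were. Among 10 measured members of the liver X receptor list, some of which act in cholesterol export, 3 were lower when adjusted over the list alone. These were Apoe, Abca1 and Pltp, at -0.99, -0.92 and -0.38. Mylip and Smpdl3a stood at -0.105 and -0.116. Lpcat3, Nr1h3, Abcg1, Apoc1 and Nr1h2 lay above 0, at 0.104, 0.059, 0.0555, 0.0406 and 0.0363. Camera did not call this list (p 0.118). Further genes chosen after their values were seen did not pass over all features. Cyp27b1, which makes active vitamin D, had a log2 fold change of -1.53 ± 0.37 (SE), and Nupr1, a stress-response factor, of -1.61 ± 0.33. Gstm1, a glutathione transferase, stood at 2.38 ± 0.72, Ugt2b7 and Ugt1a1, which conjugate glucuronic acid, at 2.33 ± 0.75 and 0.63 ± 0.18, and Pir at 0.82 ± 0.15. Without vehicle replicate 3 the gene Ugt2b7 stood at 1.53. The unnamed transcripts NM_001108135 and BF556670 stood at 3.29 and -1.64. BF556670 had the smallest limma adjusted p of the comparison, 0.0813. It was called with normexp, the filter of all 6 arrays, the mean of a gene's probes, and the variance trend with robust fit. Another, XM_344619, stood at -3.43 and was not well above background on any treated array.

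The higher cholesterol synthesis list was weighed against technical and biological explanations. A higher floor of dim spots is argued against by the 18 members at least 8-fold above the highest floor. Their median was 0.259 (SE of their mean 0.0430). A fault of single probes is argued against by 17 other probes of 12 genes, 16 of the same sign. Their means per gene had a median of 0.319 (SE of the mean 0.0674, 12 genes). The standard errors in this paragraph were taken over genes of the same 6 animals and do not measure the spread between animals. Slide position stays open: treated replicate 2, in the vehicle arrays' row on another slide, stood 0.162 above the highest vehicle list mean with 1 dim member left out, but 1 array does not decide. A sterol-low state, which may lower liver X receptor targets, stays open. That list had a median of -0.0344 and a mean of -0.221 (SE of the mean 0.130, camera p 0.118). A wider rise of lipid synthesis also stays open. The fatty acid list had a median of 0.126 and a mean of 0.0931 (SE of the mean 0.0487, camera p 0.0807). The 10 splits of the 6 arrays are too few for a share under 0.05, with a camera p of 6.04e-12 for the real split (1 of 10 as small) and 3.03e-05 as the smallest of the others.

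Of the Nrf2 targets past the threshold over the list alone, 3 had other probes. For these, a fault of the chosen probe is argued against by 6 other probes, all of the same sign. The means per gene of those probes averaged 1.11 (SE 0.311, 3 genes) in the direction of the chosen probe. This SE was taken over genes and does not measure the spread between animals. No biological explanation other than the treatment was tested.

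Hmox1 in treated replicate 3 lay 6.53 above the highest other array on the log2 scale. A fault of the spot stays open, since there were 0 other Hmox1 probes to compare. That array had 94 features at least 2-fold above all others, where the other arrays had 21 to 67.

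The 10 splits are also too few for a share under 0.05 for the counts. Features at an unadjusted p under 0.05 were 2548 in the real split and at most 1711 in the others (1 of 10 as many), features past the threshold 0 and at most 4 (10 of 10), and lists called 8 and at most 9 (3 of 10). The interferon list had a camera adjusted p of 1.08e-05 in the real split and 1.82e-08 as the smallest of the others (3 of 10 as small), organic anion transport 0.00146 and 2.99e-05 (2 of 10), and immediate early genes 0.0184 and 0.00655 (3 of 10). The smaller values of the interferon list, 1.82e-08 and 2.3e-07, came from vehicle replicates 1 and 3 grouped with treated replicate 3 or with treated replicate 2. The smallest of the others was 0.0135 for Nrf2 targets, 0.0194 for the unfolded protein response, 0.208 for heat shock and 0.0121 for erythrocyte genes, each above its real value of 0.000324, 0.000324, 0.0238 and 0.00341.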
